A study of Rattus norvegicus with 54 samples.

How the data were processed

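Bulk RNA sequencing was measured in the nucleus accumbens of Long Evans rats, in 54 libraries that fall into 8 groups by sex, age and exposure. The values used here are raw read counts per gene, deposited by the authors in 1 table with 1 column per library. Per the labels, RNA came from a high-lipid extraction, cDNA was made with random hexamers, and the libraries were not strand-specific, so reads of overlapping genes on opposite strands cannot be told apart. The submitters list fastp and HISAT2 2.0.5; the read counter, the annotation release and the genome build are not given in the sources used here. Per the labels, every RNA integrity number lay above 6.3 except a single value of 5.8, with an average of 7.2. The same table holds 54 columns of FPKM values deposited by the authors, which were not used, because the raw counts of the same libraries were present.

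The table holds 46505 genes and loci. Of these, 720 carry no gene name; they were kept out of the tests and took between 0.271% and 0.412% of a library's counts. The other 45785 were used, and the IDs of 45780 of them matched an annotation of the rat assembly GRCr8 with identical start and end. Chromosome positions given here are those of the deposited table. Total counts ran from 59.1 to 103.8 M per library, with a median of 72.5 M, and the 10 most abundant genes took a median of 3.3% of a library's counts. Reads carry no molecular identifiers, so depth speaks for counting error alone.

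Groups were taken from the sample titles, and replicate numbers follow the order of deposition. The labels give 1 batch date for all libraries and no litter, and they do not say that each library comes from a separate animal. All p-values treat the libraries as independent, which holds only if they do, and littermates would make them too small. No library was left out for its sex markers or for any other measured value in the values reported first.

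Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the edgeR default filter on low counts by group, and the quasi-likelihood F test, which is two-sided. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, with a threshold of 0.05. By chance alone a share of 0.05 of the genes tested is expected at an unadjusted p under 0.05. Each fit had 4 group means and a shared estimate of the spread. The 29 adolescent libraries gave 24741 genes tested and a biological coefficient of variation of 34.2%. The 25 adult libraries gave 24018 genes and 39.6%, and the 30 control libraries gave 24065 genes and 35.4%. From these 3 fits came 13 comparisons, which are the exposure effect in each sex, the mean over the sexes and the difference between the sexes at each age, the age effect in controls of each sex and its difference, and the sex effect in controls of each age. In the adult groups the prenatal and the adolescent exposure come together, so their effects cannot be told apart. Fold changes are on the log2 scale with their standard error (SE), and means in CPM, with library sizes scaled by TMM, are given with the standard deviation (SD).

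Named genes were chosen by a rule. Among genes past the threshold with a symbol that is not a locus identifier and a mean of at least 1 CPM, these are the 10 that rose and the 10 that fell with the smallest adjusted p. Where fewer than 5 genes passed, the 3 genes in each direction with the smallest p are given as values that did not pass. For each gene list described, up to 4 members past the threshold with the largest change are named, or up to 2 with the smallest p where none passed. Drd1, Drd2, Penk, Pdyn, Oprm1, Fkbp5, Fos, Bdnf, Xist and Kdm5d are reported where relevant. A few genes that the rule names are left out of the text and the figures.

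In all, 40 gene lists of cell types, neighbouring tissues, signalling systems and cellular processes were written down, and 39 were tested. Of their genes, 4 were matched by a synonym and 14 were not matched; 13 of the 14 are encoded by the mitochondrial genome, so the mitochondrially encoded list could not be tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 39 lists of a comparison. Beside it stand camera with an estimated correlation, fry, and the count of members past 0.05 when adjusted over the list alone. A list score is the mean over its members of log2 CPM, centred per gene over the 54 libraries. The design, the comparisons, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

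The alternatives were size factors by the relative log expression method, no filter on low counts, DESeq2 1.42.0, all 54 libraries in 1 fit, voom with sample quality weights, 2 surrogate variables from sva 3.50.0, leaving out outlying libraries, leaving out the libraries whose sex markers went against their label, and, for comparisons with a group of 5 or fewer, leaving out each library in turn. After the data were seen, 4 were added: adjustment for the share of long non-coding RNA (lncRNA) counts, adjustment for 3 scores of neighbouring tissue, leaving out each control library in turn for age and sex, and list tests without outlying libraries or without those against their sex label. A library went against its label of male where Xist was above 100 CPM and the mean of 4 Y-linked genes (Kdm5d, Ddx3y, Eif2s3y and Uty) below 10 CPM, and against its label of female in the opposite case. A library was outlying where its median Spearman correlation with the others of its fit lay over 3 median absolute deviations below the median library. Each count of genes was set against 100 splits of the libraries into groups of the same sizes, with a fixed seed and the real split among them.

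The tests were run on simulated data with the libraries' own means and spread, in which 200 genes changed by 1.5, 2, 3 or 4-fold. At a 2-fold change, edgeR recovered 84% of the changed genes in adolescent males, 90% in adolescent females, 84% in adult males and 76% in adult females for the exposure effect. The recovery was 84% for age in males and 92% in females, and for the differences between sexes 50% in adolescents, 46% in adults and 74% for age. At a 1.5-fold change the exposure recovery was 78% in adolescent males, 56% in adolescent females, 46% in adult males and 52% in adult females. For the differences between sexes it was 42% in adolescents, 20% in adults and 42% for age. Each figure rests on 50 genes of a single simulation, drawn at 1 CPM or more and independent of each other. For age in males, 5% of the edgeR calls were false, against 5.1% by limma-voom and 13% by DESeq2. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.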

Results

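The series profiled bulk RNA of the nucleus accumbens, a ventral part of the striatum that handles reward, in male and female Long Evans rats with and without ethanol exposure. Animals were exposed before birth through ethanol (PAE) or came from dams with a free-choice liquid diet (FCL), and later received water (VEH) or adolescent alcohol (AAE). Adolescents were sampled at postnatal day 42 (P42), 24 h after the last adolescent exposure, and adults at P90. At P42 there were 9 FCL-VEH and 9 PAE-VEH libraries of males, and 7 FCL-VEH and 4 PAE-VEH libraries of females. At P90 there were 6 FCL-VEH and 6 PAE-AAE libraries of males, and 8 FCL-VEH and 5 PAE-AAE libraries of females. FCL-VEH is called control from here on. Depth ran from 59.1 to 103.8 M counts per library, and the group medians from 67.7 M in PAE-VEH females at P42 to 80.6 M in control males at P90.

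Xist, the RNA that silences an X chromosome in females, and 4 Y-linked genes separated the sexes in 51 of 54 libraries. CPM in this paragraph are per total count, without TMM. In the library labelled female control replicate 5 at P42, Xist stood at 0.78 CPM and Kdm5d, a Y-linked histone demethylase, at 45.19 CPM. In the library labelled male control replicate 8 at P42, Xist stood at 725.88 CPM and Kdm5d at 0 CPM. The library labelled male PAE-VEH replicate 5 at P42 held 620.65 CPM of Xist and 0.06 CPM of Kdm5d. These 3 libraries stayed in their labelled groups, and counts without them are given where they differ.

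**Figure D1:**
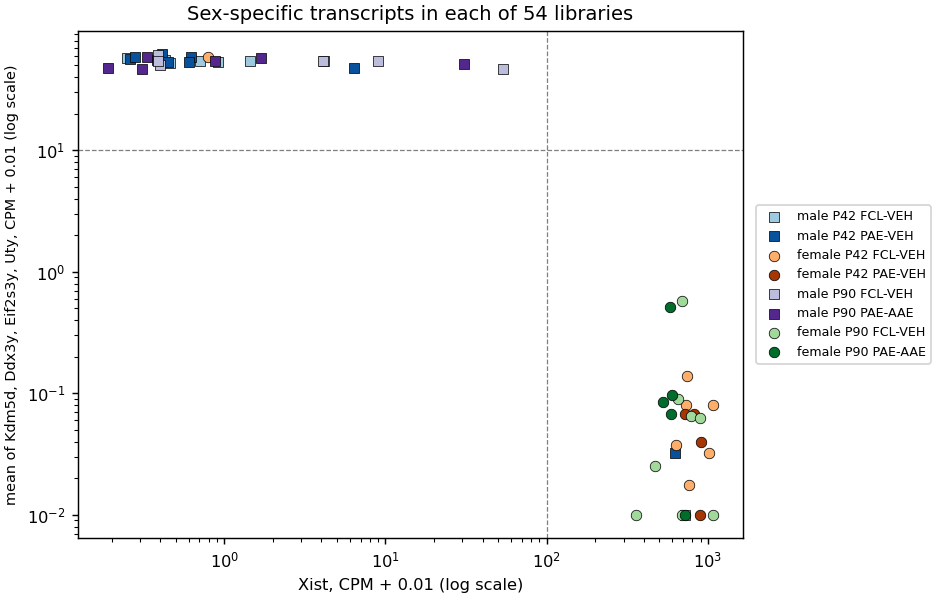
Each point is a library, with Xist on the x axis and the mean of 4 Y-linked genes on the y axis, in CPM on log axes, coloured by group (circles for libraries labelled female, squares for male). The 3 libraries that lie with the opposite sex are all from P42, with Xist at 0.78, 725.88 and 620.65 CPM.

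The age comparison in control males asked what changes in this tissue between adolescence and adulthood without ethanol. P42 controls were sampled 24 h after the last adolescent exposure, and no such interval is given for P90 controls. In both sexes, age and time since that exposure therefore cannot be told apart. Aadat, which converts kynurenine to kynurenic acid, rose most firmly, by 1.64 ± 0.17 (log2, SE), from 4.93 ± 1.22 CPM (SD, n = 9) at P42 to 15.4 ± 4.51 CPM (n = 6) at P90 (chromosome 16, 34520236 to 34566388). Qdpr, which regenerates tetrahydrobiopterin, the cofactor of dopamine synthesis, rose by 1.65 ± 0.24, from 85.8 ± 12.8 to 270 ± 118.3 CPM. Gpr17, a receptor of maturing oligodendrocytes, fell by 0.81, from 162 ± 17.5 to 92.4 ± 12.4 CPM. The adjusted p (edgeR) was 1.41e-06 for Aadat, 0.000669 for Qdpr and 0.00231 for Gpr17, and each moved the same way in all 6 adult libraries against the adolescent median.

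Other genes with a small adjusted p that rose in males were Chi3l1 (0.61), Cbs (0.51), S100a1 (0.87), Rnase4 (0.62), Aass (0.64), Mgst1 (0.90), Sult1a1 (1.23) and Selenbp1 (0.93). Cbs makes cystathionine and Aass degrades lysine. Those that fell included Elovl6 (-0.53), Rab7b (-0.72), Aacs (-0.53), Adam19 (-0.73), Casr (-0.86), Tbc1d13 (-0.24), Abca3 (-0.34) and Fbxl18 (-0.57). Elovl6 extends fatty acids. Altogether 465 genes rose and 145 fell of 24065 tested, with a median absolute log2 change of 0.49, and 45 rose and 20 fell by over 1 on the log2 scale. Fos, an activity-induced transcription factor, rose by 1.0 ± 0.27 (adjusted p = 0.0417; higher in 5 of 6), a call that held in 4 of 15 fits with 1 library left out, while Drd1 (-0.20), Drd2 (-0.08), Penk (-0.02) and Pdyn (-0.28) did not pass.

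Among gene lists in control males, 16 of 25 ribosomal protein genes rose, among them Rps3 (0.58) and Rpl23 (0.58), and 25 when adjusted over the list alone (camera adjusted p = 4.28e-20). The median change was 0.46, and the adjusted p = 0.177 with an estimated correlation. The lncRNA share of counts, with which this list moves, was 0.99% at P90 and 1.13% at P42 on average. Of 18 cholesterol synthesis genes 7 fell, among them Hmgcs1 (-0.59) and Dhcr7 (-0.47), and 12 when adjusted over the list alone, with an adjusted p = 0.176 with an estimated correlation. Of 20 interferon response genes 4 rose, among them Psmb9 (0.95) and Psmb8 (0.89) of the immunoproteasome and B2m (0.50), and 10 when adjusted over the list alone (adjusted p = 0.176 with an estimated correlation). Of 17 microglial genes the 3 complement genes C1qa (0.74), C1qb (0.72) and C1qc (0.74) rose, and 10 when adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). Of 14 astrocyte genes S100b (0.61) and Aldoc (0.53) rose, and 7 when adjusted over the list alone (adjusted p = 0.177 with an estimated correlation). With 1 library left out, C1qa and C1qc passed in 5 of 15 fits and C1qb in 7, Rps3, Rpl23, B2m and Aldoc in 13, and Dhcr7 and Psmb9 in 14.

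The perineuronal net and brain matrix list was shifted down in control males at both settings of the test (median -0.30; camera adjusted p = 0.00133, and adjusted p = 0.0396 with an estimated correlation). Of its 20 genes, Ncan, a brain proteoglycan, fell (-0.48 ± 0.12), and 6 fell and 1 rose when adjusted over the list alone. Of 25 glutamate signalling genes Grik2 (-0.35) and Grin1 (-0.30) fell, 4 when adjusted over the list alone (adjusted p = 0.176 with an estimated correlation). With 1 library left out, Ncan and Grin1 passed in 12 of 15 fits. Markers of choroid plexus, a neighbour of this tissue, were higher at P90 in males, with a median of 0.99 over 13 genes and none past the threshold. The choroid plexus list did not pass at both settings of the test, as the perineuronal list alone did. Male counts moved with single libraries. They were 106 without adult replicate 6, 176 without adult replicate 4, 1102 without adult replicate 1 and 1207 without adult replicate 2, and 306, 356, 368 and 394 without P42 replicates 7, 3, 2 and 8. They were 322 without the libraries whose sex markers went against their label and 250 without the outlying libraries. Adult replicate 6 is outlying. Its Xist stood at 56.7 CPM (0.36 to 9.32 in the other adult control males). Its Kdm5d, at 28.61 CPM per total count, was the lowest of its group. This library also had the highest choroid plexus and ribosomal scores of its group, 3.18 and 0.78. Whether it held RNA of both sexes was not tested. With 3 scores of neighbouring tissue as covariates 49 of the 610 genes still passed, all 610 kept their direction, and the median absolute log2 change went from 0.50 to 0.40.

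The same comparison in control females gave 54 genes that rose and 47 that fell between P42 (n = 7) and P90 (n = 8). Nat8f3, of the N-acetyltransferase 8 family, rose by 1.68 ± 0.21, from 28.2 ± 7.89 to 90.02 ± 29.6 CPM (edgeR adjusted p = 8.26e-05; higher in 8 of 8). Aadat rose by 1.02, Qdpr by 1.30, Cbs by 0.45 and Aass by 0.53, and Camkk1 (0.44), Fn3k (0.43), Samd9l2 (0.68), Cbx7 (0.36) and Cyp4f4 (0.64) also rose. Casr, the calcium-sensing receptor (-1.0), Gpr17 (-0.81), Rnf122 (-0.92), Sqle (-0.40), Rab7b (-0.67), Elovl6 (-0.46), Mkrn3 (-1.09), Nid1 (-0.72) and Adam19 (-0.66) fell.

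In control females 6 of 18 cholesterol synthesis genes fell, among them Hmgcs1 (-0.53), Dhcr7 (-0.52) and Cyp51 (-0.52), and 8 when adjusted over the list alone (median -0.25; adjusted p = 0.392 with an estimated correlation). No gene of the proliferation list passed in the edgeR test over all genes, where 3679 genes lay at an unadjusted p under 0.05, but 15 of 20 fell when adjusted over the list alone (median -0.87; adjusted p = 0.392 with an estimated correlation). Ependymal cilia genes, of a neighbouring tissue, moved with them, with a median of -0.88 (adjusted p = 0.429 with an estimated correlation) and a mean score of 0.79 at P42 and -0.26 at P90. Of the 14 oligodendrocyte precursor genes Enpp6 (-1.11), Gpr17 and Vcan (-0.44) fell, and of the 20 myelin genes Ugt8 (-1.17), which makes galactocerebroside (adjusted p = 0.429 and 0.524 with an estimated correlation). Ifit3 (1.42) and Psmb8 (0.76) of the interferon response, the activity-induced Fosb (0.97), and the glucocorticoid-induced Sgk1 (0.92) and Sult1a1 (0.88) rose. Those lists had an adjusted p = 0.429, 0.433 and 0.392 with an estimated correlation. With 1 library left out, Vcan passed in 3 of 15 fits, Sgk1 in 5, Sult1a1 in 6, Cyp51 in 7, Hmgcs1 in 12, and Psmb8 and Ugt8 in 14. Kdm5d, Ddx3y and Eif2s3y were also past the threshold, at 6.32, 15.2 and 7.47 CPM at P42 against 0.0771, 0.15 and 0.096 CPM at P90, and the P42 means rest on the library labelled female replicate 5. Female counts were 60 without adult replicate 3 or P42 replicate 3, 65 without P42 replicate 2, 171 without adult replicate 6, 290 without adult replicate 4, and 43 without the libraries whose sex markers went against their label.

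Between the sexes, 20 genes rose with age in both where chance gives 1.04, and 18 fell in both where chance gives 0.28, out of 24065. Those that rose in both included Aadat, Aass, Cbs, Qdpr, Fosb, Psmb8 and Selenbp1. Those that fell in both included Hmgcs1, Sqle, Cyp51, Dhcr7 and Lss of cholesterol synthesis, with Gpr17, Casr and Elovl6. No gene was called in opposite directions, 555 of the 610 male genes had the same sign in females, and 94 of the female genes had the same sign in males. Both sexes were tested in the same fit but on separate libraries.

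**Figure D2:**
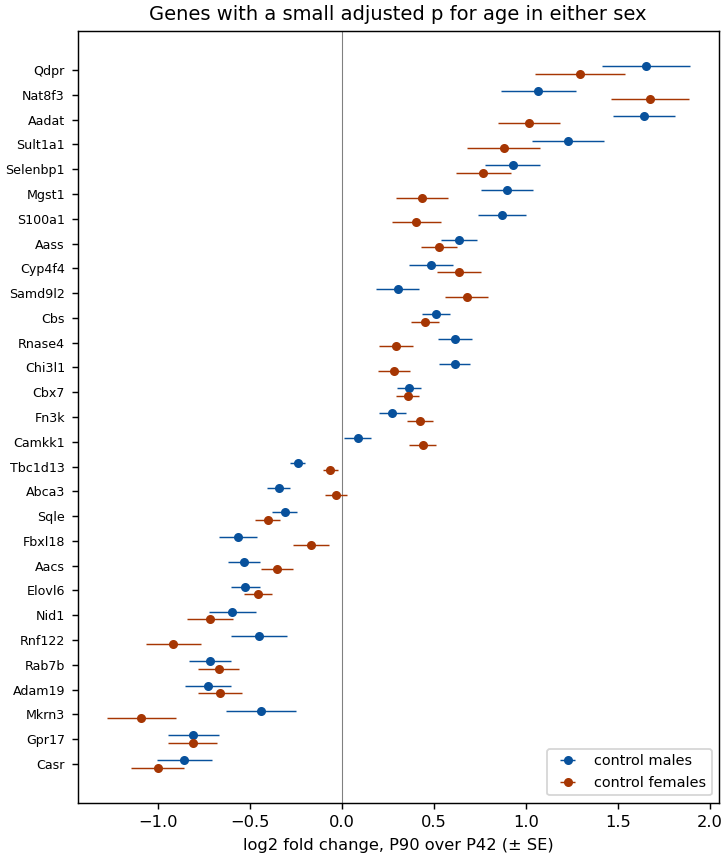
Log2 change from P42 to P90 in control males and control females, with bars of 1 SE, for genes with a small adjusted p in either sex (males n = 6 and 9, females n = 8 and 7). Aadat rose by 1.64 in males and 1.02 in females, and Gpr17 stood at -0.81 in both.

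The difference of the age effect between sexes was tested on its own, as female minus male. Ptprm (0.39 ± 0.09), Lamb1 (0.49) and Rptor (0.25) on the positive side, and Tgfbi (-1.22), Krt18 (-1.94) and Aif1l (-0.75) on the negative side had the smallest p, with an adjusted p of 0.47 each. The ependymal cilia list was shifted down (median -1.43; 7 of 14 when adjusted over the list alone; camera adjusted p = 1.38e-09, and adjusted p = 0.417 with an estimated correlation). The choroid plexus list had a median of -1.79 (adjusted p = 0.504 with an estimated correlation). By edgeR 0 of 24065 genes passed, with 2045 at an unadjusted p under 0.05, and DESeq2 and voom each gave 0.

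The effect of prenatal ethanol in adolescent males compared 9 PAE-VEH with 9 control libraries. Among these, PAE-VEH replicate 5 and control replicate 8 carried female sex markers. Values with the smallest p that did not pass were Fabp7, a fatty acid binding protein of radial glia and astrocytes, at 77.8 ± 10.5 against 55.7 ± 4.48 CPM (0.48 ± 0.10; higher in 9 of 9; edgeR adjusted p = 0.228), Ndp (0.30) and Nat9 (0.33). On the lower side were Trappc3l (-0.57), Ica1l (-0.21) and Tbkbp1 (-0.38). Drd1 (-0.01), Drd2 (-0.04), Penk (0.06), Pdyn (0.00), Oprm1 (-0.18), Fkbp5 (0.08), Fos (0.53) and Bdnf (0.70) did not pass. Without PAE-VEH replicate 6, the outlying library of this fit, with Bdnf at 15.8 CPM and a cortical score of 2.91, the values were 0.30 for Fos and -0.73 for Bdnf. By edgeR 0 of 24741 genes passed, with 2217 at an unadjusted p under 0.05; DESeq2 gave 24 and voom 1.

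Lists shifted up in PAE-VEH adolescent males were led by ribosomal proteins and by heat shock and protein folding. All 25 ribosomal protein genes were higher, with a median of 0.18 and 16 that rose when adjusted over the list alone, such as Rplp0 (0.24) and Rpl38 (0.33), and the adjusted p = 0.307 with an estimated correlation. The lncRNA share was 1.02% ± 0.153% (SD) in PAE-VEH and 1.13% ± 0.168% in control males. Of 18 heat shock and folding genes all were higher (median 0.20), and 9 rose when adjusted over the list alone, such as the chaperones Hsp90b1 (0.21) and Calr (0.24), with an adjusted p = 0.0821 with an estimated correlation. The proliferation list had a median of 0.62, and 6 of 20 rose when adjusted over the list alone, such as Pcna (0.31) and Cdca8 (0.61), with an adjusted p = 0.543 with an estimated correlation. Of the 9 septal and pallidal neighbour genes 8 were higher (median 0.59; adjusted p = 0.476 with an estimated correlation). The endothelial list was shifted down (median -0.21; adjusted p = 0.543 with an estimated correlation). Without the outlying PAE-VEH replicate 6, which had the highest ribosomal score of its group (0.20), 10 of the 14 lists past the threshold still passed, with medians of 0.15 for ribosomal, 0.16 for heat shock and 0.71 for proliferation genes, and -0.33 for endothelial genes.

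In adolescent females, 4 PAE-VEH libraries were compared with 7 controls, of which replicate 5 carried male sex markers. Penk, the precursor of enkephalins in D2 receptor neurons, stood at 1299 against 762 CPM (0.77 ± 0.18; higher in 4 of 4; edgeR adjusted p = 0.147) and did not pass. Nor did Drd2 (0.49), Pdyn (0.49), Drd1 (0.32) or Fkbp5 (0.29). The smallest p belonged to Ssbp4 (0.38 ± 0.07), Ajm1 (0.33) and Gpat3 (0.92) on the higher side, and Sncg (-1.34), Rb1 (-0.29) and Il15 (-1.20) on the lower, all with an adjusted p of 0.129. By edgeR 0 of 24741 genes passed, with 2786 at an unadjusted p under 0.05; DESeq2 gave 86 and voom 36.

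All 21 medium spiny neuron genes, markers of the main striatal neurons, were higher in PAE-VEH adolescent females, with a median of 0.39 and 5 that rose when adjusted over the list alone (camera adjusted p = 1.51e-12, and adjusted p = 0.458 with an estimated correlation). Ppp1r1b, known as DARPP-32, stood at 1978 ± 251 against 1388 ± 254 CPM, and Arpp21 at 0.43 on the log2 scale. Of 7 D2 receptor neuron genes 5 rose when adjusted over the list alone, such as Gpr6 (0.54), with an adjusted p = 0.458 with an estimated correlation. Of 20 immediate early genes 11 rose when adjusted over the list alone, such as Nr4a1 (1.06) and Egr4 (0.84), and the median was 0.47 (adjusted p = 0.428 with an estimated correlation). Markers of neighbouring tissue moved with these lists. Septal and pallidal genes had a median of -0.88, 9 of 9 lower, and ependymal cilia genes -0.81 (adjusted p = 0.657 and 0.785 with an estimated correlation). PAE-VEH replicate 4 had a cortical excitatory neuron score of 2.10 (-0.57 to -0.52 in the other PAE-VEH females). List tests without that library were not run. The myelin list was shifted down (median -0.33; adjusted p = 0.022, and adjusted p = 0.879 with an estimated correlation), which ended without the libraries whose sex markers went against their label (adjusted p = 0.327).

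**Figure D3:**
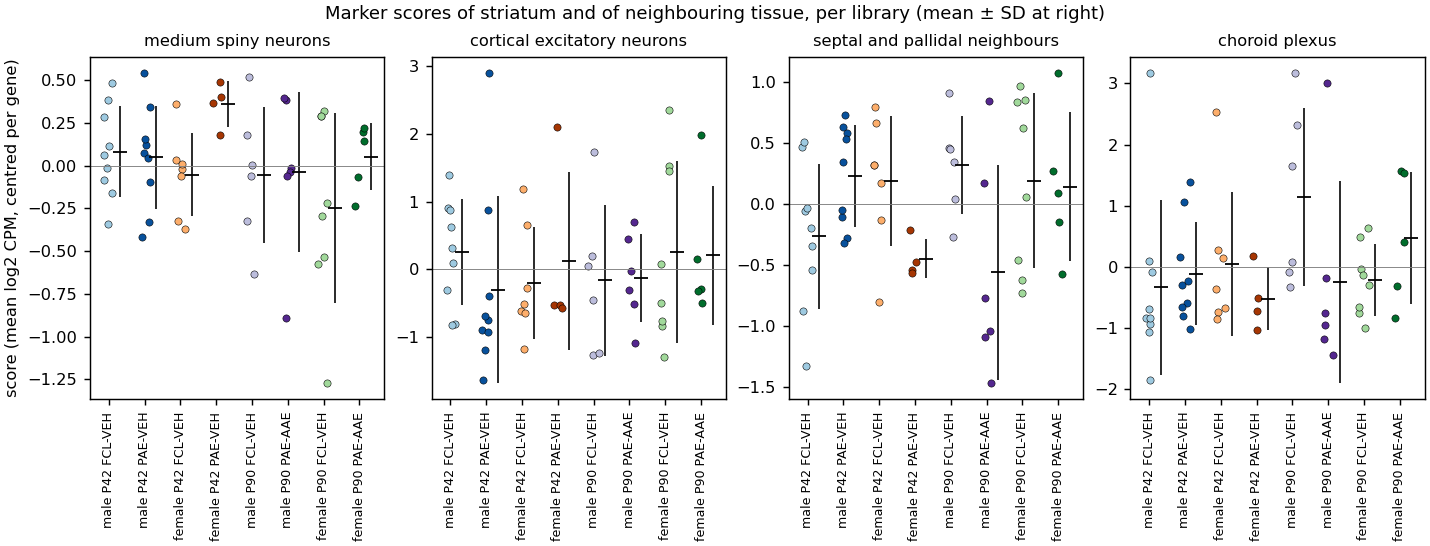
List scores per library (points) with the group mean and SD, as mean log2 CPM centred over the 54 libraries, for medium spiny neurons, cortical excitatory neurons, septal and pallidal neighbours and choroid plexus in each of the 8 groups. At P42 the female PAE-VEH mean is 0.36 for medium spiny neurons and -0.45 for septal and pallidal genes, against -0.05 and 0.19 in female controls.

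Averaged over both sexes, prenatal ethanol gave 0 of 24741 genes past the threshold in adolescents by edgeR, with 2698 at an unadjusted p under 0.05; DESeq2 gave 21 and voom 0. Tmem276 (0.31), Htra1, a secreted protease (0.40), and Cbs (0.19) on the higher side and Trappc3l (-0.52), Il15 (-0.72) and Znf431l5 (-0.21) on the lower had an adjusted p of 0.196. Immediate early genes were shifted up (median 0.32; 10 of 20 when adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), with Nr4a1 at 0.71 ± 0.16. So were glucocorticoid-induced genes (median 0.18; 4 of 14 when adjusted over the list alone; adjusted p = 0.199 with an estimated correlation), with Ddit4 at 0.18 and Sgk1 at 0.25.

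Whether prenatal ethanol acted differently by sex was tested as the female minus the male effect. Ajm1 (0.47 ± 0.08, adjusted p = 0.0721), Ssbp4 (0.45) and Shc2 (0.50) were on the positive side, and Fabp7 (-0.88 ± 0.16, adjusted p = 0.0822), Dbi (-0.64) and Hmgb1 (-0.39) on the negative, none past the edgeR threshold. The medium spiny neuron list was higher in females by a median of 0.41 (21 of 21; adjusted p = 0.529 with an estimated correlation). Proliferation genes had a median of -1.10 and septal and pallidal genes of -1.47, with 1 of 20 and 8 of 9 that fell when adjusted over the list alone (adjusted p = 0.535 and 0.523 with an estimated correlation). By edgeR 0 genes passed, with 2617 at an unadjusted p under 0.05; DESeq2 gave 72 and voom 81. Leaving out any of 6 single libraries gave between 1 and 7 genes, 7 without female control replicate 3. Leaving out the libraries whose sex markers went against their label gave 1 gene.

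In adult males, 6 PAE-AAE libraries, with both prenatal and adolescent ethanol, were compared with 6 controls. Sorcs1, a sorting receptor (0.39 ± 0.09), Noc3l (0.31) and Skic3 (0.36) had the smallest p on the higher side, and Spetex2l2 (-1.49), Cndp1, a dipeptidase (-1.15), and Lsp1 (-1.15) on the lower, with an edgeR adjusted p of 0.552 each. Drd1 (0.17), Drd2 (0.07), Penk (0.13), Pdyn (0.35) and Oprm1 (0.48) did not pass. All 25 ribosomal protein genes were lower (median -0.35; 23 fell when adjusted over the list alone; adjusted p = 0.575 with an estimated correlation), such as Rps3 at 252 ± 23.1 against 353 ± 103.8 CPM. All 25 nuclear-encoded oxidative phosphorylation genes were lower (median -0.31; 15 fell when adjusted over the list alone; adjusted p = 0.575 with an estimated correlation), such as Ndufa2 (-0.53) and Cox7b (-0.46). The lncRNA share was 1.17% ± 0.098% (SD) in PAE-AAE and 0.99% ± 0.196% in control males. Control replicate 6, an outlying library, had the lowest share of the controls, 0.768%, and their highest ribosomal score.

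Glial and neighbour lists were shifted down in the same PAE-AAE males. The median was -0.49 for microglia, with C1qb at -0.59 and Aif1 at -0.60, and -0.47 for myelin, with Mbp at 4319 ± 904 against 8205 ± 5206 CPM. Choroid plexus genes had a median of -0.76 and septal and pallidal genes of -0.79. The adjusted p with an estimated correlation was 0.575, 0.684, 0.575 and 0.575 for these lists, and no member passed by edgeR or when adjusted over the list alone. Control replicates 4 and 6 stood highest, with scores of 1.13 and 0.82 for myelin against -0.49 to -0.02 in the other controls, 0.71 and 0.76 for microglia, and 2.32 and 3.18 for choroid plexus. Without the outlying libraries, control replicate 6 among them, the medians were -0.35 for myelin, -0.38 for microglia and -0.22 for choroid plexus. By edgeR 0 of 24018 genes passed, with 2100 at an unadjusted p under 0.05; DESeq2 gave 2 and voom 1.

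In adult females, 5 PAE-AAE libraries were compared with 8 controls. Klhdc7a stood at 23.9 ± 3.10 against 12.7 ± 3.47 CPM (0.91 ± 0.16) and Htra1 at 131 ± 15.4 against 90.9 ± 9.70 CPM (0.52 ± 0.10), each higher in 5 of 5 with an edgeR adjusted p of 0.114. Vgf, a neuropeptide precursor (0.38), Spetex2l2 (-1.57), Cirbp (-0.42) and Edem1 (-0.27) followed. Drd1 (0.15), Drd2 (0.24), Penk (0.37) and Pdyn (0.18) did not pass. All 18 heat shock and folding genes were higher (median 0.26; 5 rose when adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), such as Hspb1 at 11.7 ± 1.92 against 5.33 ± 2.43 CPM and Hspa5 (0.50). Immediate early genes had a median of 0.41 (1 of 20 when adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), with Nr4a1 at 96.2 ± 7.55 against 46.3 ± 15.6 CPM. PAE-AAE replicate 3 had a cortical excitatory neuron score of 1.99 (-0.49 to 0.16 in the other PAE-AAE females). List tests without that library were not run. Blood genes had a median of 1.95 and choroid plexus genes of 0.65 (adjusted p = 0.334 and 0.761 with an estimated correlation). By edgeR 0 of 24018 genes passed, with 1015 (4.23%) at an unadjusted p under 0.05. That is below the share of 0.05 expected by chance alone. DESeq2 gave 8 and voom 1.

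Averaged over both sexes, 1 gene passed in exposed adults, Spetex2l2, which fell by 1.53 ± 0.24 on the log2 scale (adjusted p = 0.0247; chromosome 9, 3183357 to 3253392). It stood at 10.9 ± 3.61 against 30.6 ± 7.26 CPM in males and 9.22 ± 1.009 against 27.3 ± 16.4 CPM in females, lower in 6 of 6 and 5 of 5. The call ended without any of 14 single libraries, with all 54 libraries in 1 fit, without the outlying libraries and with neighbour-tissue covariates, where its log2 change stayed between -1.62 and -1.40. Next by p were Srsf3-ps11 (0.63), Tubd1 (0.37) and Klhdc7a (0.44), and Chchd4 (-0.45) and Nt5m (-0.26), none of which passed. By edgeR 784 genes (3.26%) lay at an unadjusted p under 0.05, below the share of 0.05 expected by chance alone. Opioid and neuropeptide genes were shifted up (median 0.14, adjusted p = 0.193 with an estimated correlation), with Tacr1, the substance P receptor, at 0.30. Of 7 blood genes, median 2.09, 5 rose when adjusted over the list alone (adjusted p = 0.531 with an estimated correlation). These large medians include genes with few counts, such as Hbb-bs with a mean of 0.18 CPM.

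The difference of the adult effect between sexes gave 0 of 24018 genes by edgeR, with 2544 at an unadjusted p under 0.05, and DESeq2 and voom gave 0. The smallest p belonged to Htra1 (0.60 ± 0.14), Apln (0.61) and Tmem238 (1.08), and to Ptprm (-0.41), Fignl2-ps1 (-1.66) and Zfp534l1 (-0.84), with an adjusted p of 0.423. The ribosomal list was higher in the female than in the male effect (median 0.56; 24 of 25 rose when adjusted over the list alone; camera adjusted p = 8.68e-18, and adjusted p = 0.646 with an estimated correlation), with Rps3 at 0.70. Oxidative phosphorylation genes followed (median 0.46, 25 of 25 positive, adjusted p = 0.646 with an estimated correlation). The lncRNA share, with which both lists move, also went opposite ways. On average it was higher in PAE-AAE than in control males, and lower in PAE-AAE than in control females.

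**Figure D4:**
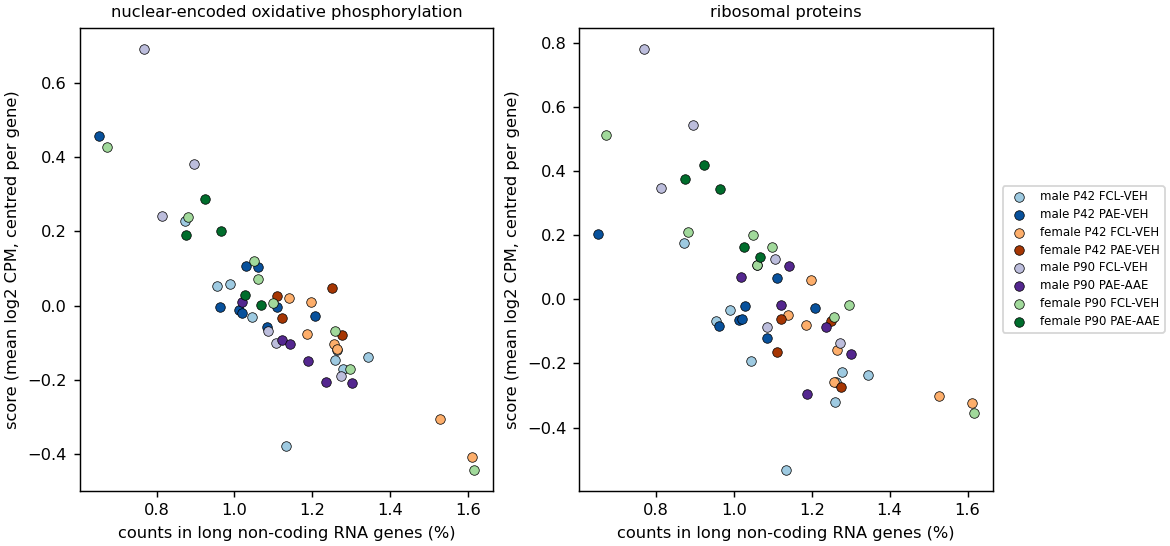
Score of the oxidative phosphorylation list and of the ribosomal protein list (y axes, mean log2 CPM centred over the 54 libraries) against the percent of counts from lncRNA genes (x axis), 1 point per library, coloured by group. Both scores are lower where the lncRNA share is higher.

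The sex comparison in adult controls, 8 females and 6 males, gave 4 genes that were higher and 8 that were lower in females, 10 of the 12 on X or Y. Ddx3x, an RNA helicase that escapes X inactivation, stood at 365 ± 16.6 against 282 ± 16.2 CPM (0.37 ± 0.06; edgeR adjusted p = 0.0113; higher in 8 of 8). Kdm6a (0.49) and Eif2s3 (0.62) were higher too, and 5 of 5 X-linked escape genes when adjusted over the list alone (adjusted p = 0.00104 with an estimated correlation). The Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty stood at 95.3, 58.9, 39.7 and 22.5 CPM in males and at 0.15, 0.096, 0.0771 and 0.057 CPM in females (adjusted p = 0.0011 with an estimated correlation for the list). Xist was at 698 ± 198 CPM in females and 12.01 ± 22.5 CPM in males, and its edgeR adjusted p was 0.808. Per total count, the lowest adult control female stood at 356.06 CPM and the highest male at 53.33 CPM. The fit shares its spread with the P42 controls, where the libraries labelled female replicate 5 and male replicate 8 stood at 0.78 and 725.88 CPM. This adjusted p therefore does not speak against a sex difference in Xist. The choroid plexus list was lower in females (median -1.65; 9 of 13 when adjusted over the list alone; adjusted p = 0.449 with an estimated correlation), and the myelin list had a median of -0.56 (2 of 20; adjusted p = 0.449 with an estimated correlation). Male replicates 4 and 6 had the highest scores of the males, 2.32 and 3.18 for choroid plexus and 1.13 and 0.82 for myelin, and without the outlying libraries, female replicate 1 and male replicate 6, the medians were -1.10 and -0.64. The count was 6 without female replicate 5 and 7 without male replicate 3, 5 with neighbour-tissue covariates and 0 by voom.

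In adolescent controls, 7 females against 9 males, Kdm6a (0.47 ± 0.08; adjusted p = 0.0864; higher in 6 of 7), Ddx3x (0.29) and Eif2s3 (0.52) had the smallest p on the higher side, and Myo15b (-0.82), Rnf112 (-0.27) and Tbc1d13 (-0.15) on the lower. By edgeR 0 of 24065 genes passed, with 1464 at an unadjusted p under 0.05; DESeq2 and voom gave 7 each. Without the libraries whose sex markers went against their label 13 genes passed, and without the library labelled male replicate 8 or female replicate 5 alone the counts were 6 and 11. The X-linked escape list and the Y-linked list passed at both settings of the test (adjusted p = 0.00417 and 0.00726 with an estimated correlation). Proliferation genes were higher in females (median 0.94; 17 of 20 rose when adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with Rrm2, of nucleotide synthesis, at 7.55 ± 4.46 against 3.49 ± 0.49 CPM and Cdca8 at 4.18 ± 1.28 against 2.35 ± 0.50 CPM. Ependymal cilia genes moved with them (median 0.80; adjusted p = 0.362 with an estimated correlation). Female replicates 1 and 5 had the lowest cilia scores of the females, 0.30 and 0.35, and the lowest proliferation scores, -0.33 and -0.26.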

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

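The tests on the sex markers, on the lncRNA share and with covariates were chosen only after the result was seen. CPM values in this part are scaled by TMM. In all, 287 groups of values were checked for 1 library far from the others, and 37 had such a library. A nominal rate of 1 in 20 gives about 14. The groups share libraries and are not independent, so 37 against 14 does not measure an excess over chance.

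In 3 libraries of P42 the sex markers lay far from their group: Xist was at 0.759 CPM in the library labelled female FCL-VEH replicate 5 (others 653 to 984), 711 CPM in male FCL-VEH replicate 8 (others 0.228 to 4.24) and 647 CPM in male PAE-VEH replicate 5 (others 0.253 to 7.08). RNA of both sexes mixed is argued against in these 3 libraries, since the lower of the markers stayed at 0.106% or less of the level of the sex that has it. Such mixing was not tested in male FCL-VEH replicate 6 at P90, with Xist at 56.7 CPM. An exchange between male and female PAE-VEH libraries is argued against too, as 0 libraries of the female PAE-VEH group at P42 went against their label. For male PAE-VEH replicate 5 a single wrong label or an exchange with a library from outside stays open. So does an exchange with female FCL-VEH replicate 5, which would make their exposure labels wrong too. Labels exchanged between male FCL-VEH replicate 8 and female FCL-VEH replicate 5 may account for that pair, with 1 library out of place in the female FCL-VEH group, and stay open. No biological explanation was tested.

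In the same libraries Kdm5d stood at 43.8 CPM (female FCL-VEH replicate 5; others 0 to 0.102), 0 CPM (male FCL-VEH replicate 8; others 41.7 to 48.3) and 0.0672 CPM (male PAE-VEH replicate 5; others 37.1 to 50.2). In female FCL-VEH replicate 5, Kdm6a was at 34.9 CPM (others 49.2 to 55.1) and Ddx3x at 275 CPM (others 349 to 375). In male FCL-VEH replicate 8, Ddx3x was at 352 CPM (others 264 to 291) and Eif2s3 at 143.6 CPM (others 85.4 to 108.5).

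Ribosomal protein and oxidative phosphorylation genes moved together, down in PAE-AAE adult males (medians -0.35 and -0.31) and up in PAE-AAE adult females (0.20 and 0.11), with no member past the edgeR threshold and an adjusted p = 0.575 for both lists in males and 0.761 and 0.768 in females with an estimated correlation. Length and expression of the genes may account for part of the ribosomal shift and stay open. In adult females the ribosomal median of 0.20 lay at percentile 100 of 10000 lists matched on both. Those lists had a median of 0.106 and a central 95% from 0.067 to 0.157. In adult males the matched lists had a median of -0.25, with -0.35 at percentile 1.11. The matched lists are random, while ribosomal genes move together between libraries. The percentile therefore cannot decide whether length and expression are the whole cause. An unequal share of lncRNA reads between libraries may account for part of the shift and stays open: over 54 libraries, as deviations from the group mean, the oxidative phosphorylation score fell with the share (r = -0.88; permutation p = 1e-05, the smallest the permutations can give; without the 2 farthest libraries -0.84). With the share as a covariate the ribosomal median for prenatal and adolescent ethanol in adult males went from -0.35 to -0.14 (adjusted p = 4.69e-09 at the preset correlation), and for prenatal and adolescent ethanol in adult females from 0.20 to 0.05 (adjusted p = 0.0877), and without the share no list passed in either sex with an estimated correlation. RNA quality or composition as the origin of that share was not measured per library, and an effect of the exposures, of both ages of exposure together in adults, stays open as untested.

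In adolescent females exposed before birth, medium spiny neuron genes were higher (median 0.39) and septal and pallidal genes lower (median -0.88). More neighbouring tissue in some libraries may account for part of it and stays open: over 54 libraries, as deviations from the group mean, the medium spiny neuron score fell as the septal and pallidal score rose (r = -0.55; permutation p = 2e-05; without the 2 farthest libraries -0.47). Whether it is the whole cause of the medium spiny neuron shift cannot be decided. With septal, cortical and choroid plexus scores as covariates the adjusted p was 1.81e-12 (camera, preset correlation) and the median 0.28. These covariates left out the ependymal cilia genes, which moved as well, and the preset correlation takes the genes of the list as nearly independent. An effect of prenatal ethanol stays open as untested, and with an estimated correlation between genes the list had an adjusted p = 0.458.

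Other single libraries lay far from the rest of their group in a named gene. Bdnf was at 15.8 CPM in male PAE-VEH replicate 6 at P42 (others 0 to 2.11), 4.9 CPM in male FCL-VEH replicate 1 at P42 (others 0.475 to 2.39), 7.1 CPM in female PAE-VEH replicate 4 at P42 (others 0.26 to 0.369), 5.63 CPM in male FCL-VEH replicate 1 at P90 (others 0.638 to 1.43) and 8.02 CPM in female PAE-AAE replicate 3 (others 0.67 to 2.39). The cortical excitatory neuron score of these 5 libraries was 2.91, 1.39, 2.10, 1.74 and 1.99, the highest of the group in each case. At P42, Nat9 was at 25.6 CPM in male PAE-VEH replicate 7 (others 17.4 to 21.2), Tbkbp1 at 67.4 CPM in male PAE-VEH replicate 3 (others 36 to 48.7), Ajm1 at 191 CPM in female PAE-VEH replicate 1 (others 160 to 164) and Kdm5d at 0.0583 CPM in female PAE-VEH replicate 2 (others at 0). At P90, Oprm1 was at 13.5 CPM in male PAE-AAE replicate 3 (others 7.18 to 9.25), Xist at 30.04 CPM in male PAE-AAE replicate 5 (others 0.183 to 1.62) and 56.7 CPM in male FCL-VEH replicate 6 (others 0.36 to 9.32), and Gpr17 at 117 CPM in male FCL-VEH replicate 4 (others 82.4 to 92.7). In female FCL-VEH replicate 8 at P90, Kdm5d was at 0.527 CPM, Eif2s3y at 0.545, Ddx3y at 0.718 and Uty at 0.425 (others up to 0.0541, 0.106, 0.179 and 0.0303). In female FCL-VEH replicate 1 at P90, Qdpr was at 436 CPM (others 125.9 to 248), Gpr17 at 130 CPM (others 65 to 90.5) and Eif2s3 at 212 CPM (others 135 to 170).

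Scores of tissue markers and the lncRNA share also set single libraries apart. The choroid plexus score was 3.18 in male FCL-VEH replicate 5 at P42 (others -1.85 to 0.10), 2.53 in female FCL-VEH replicate 7 at P42 (others -0.86 to 0.27) and 3.005 in male PAE-AAE replicate 6 (others -1.45 to -0.19). The cortical excitatory neuron score was 2.1 in female PAE-VEH replicate 4 at P42 (others -0.57 to -0.52) and 1.99 in female PAE-AAE replicate 3 (others -0.49 to 0.16). The medium spiny neuron score was -0.89 in male PAE-AAE replicate 3 (others -0.06 to 0.40). The lncRNA share was 0.651% in male PAE-VEH replicate 6 at P42 (others 0.963% to 1.21%). Among 636 loci without a gene name, kept out of the comparisons, 4 passed the threshold with age in control males (3 rose, 1 fell) and 1 rose in control females.

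Each count of genes was set against other splits of the same libraries, 100 per comparison with the real one among them. For age in controls chance is argued against, with 1 split of 100 as large, the real one, the smallest share this test can give. In males 610 genes stood against a highest other of 422, and in females 54 that rose and 47 that fell against 57. The 422 also points to a structure of the samples. The male count was 106 without adult replicate 6 and 51 with neighbour-tissue scores as covariates. For sex in adult controls 3 of 100 splits were as large, the real one among them, with 12 genes against a highest other of 906. That is fewer than the 5 of 100 set as the limit, but other splits reached the count, so it does not exclude chance by itself. Of the 12 genes, 10 lie on X or Y. A split with 906 genes points to a structure of the samples. For the mean of the sexes in adults chance cannot be excluded, with 5 of 100 splits as large and 1 gene against a highest other of 379, which points to a structure of the samples as well. In the other 9 comparisons edgeR gave a real count of 0, which all 100 splits reach whatever the data. The splits therefore say nothing about chance there. At an unadjusted p under 0.05 those comparisons held between 1015 and 2786 genes (4.23% to 11.26%), where chance alone gives a share of 0.05. In them DESeq2 gave 0 to 86 genes and voom 0 to 81. The highest other count there was 1 in adolescent males, 85 in adolescent females, 96 for their mean and 30 for their difference, 9 in adult males, 2 in adult females and 717 for their difference, 2955 for the difference of the age effect and 0 for sex in adolescent controls. The counts of 85, 96, 717 and 2955 point to a structure of the samples, and the cause was not tested.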

How the results depend on the processing

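The tests with the lncRNA share and with neighbour-tissue scores as covariates, leaving out each library in turn for age and for sex in controls, and list tests without outlying libraries, were chosen only after the result was seen. Named genes past the threshold were counted once in each comparison that called them, which gave 100 calls. Of these, 100 kept direction and call with relative log expression size factors, 97 with 2 surrogate variables and 97 with the lncRNA share. With 54 libraries in 1 fit 95 kept both, 93 by DESeq2, 85 without a filter, 83 by voom and 77 without outlying libraries. Without the libraries whose sex markers went against their label 75 kept both, 22 lost the call and 2 reversed. Spetex2l2 has no such value, as those libraries are from P42. With neighbour scores 59 kept both. Lists were counted in the same way. Of 192 list calls, 5 stayed past the threshold with an estimated correlation, 21 by fry and 164 without outlying libraries. With the lncRNA share 147 stayed, and 141 with neighbour scores. Without the libraries against their sex label 14 lost their call, and 6 of the 11 lists called for the mean effect in adolescents still passed. Compared with edgeR counts of 610 (age, males), 54 up and 47 down (age, females), 12 (sex, adults), 1 (mean effect, adults) and 0 elsewhere, counts moved by over 1.5 times as follows. Without a filter: 360 for age in males, 60 in females. By DESeq2: 24 in adolescent males, 86 in adolescent females, 21 for their mean and 72 for their difference; 2 in adult males, 8 in adult females, 5 for their mean; 1166 for age in males, 349 in females; 7 for sex in adolescents. With 54 libraries in 1 fit: 0 for the mean in adults, 938 for age in males, 178 in females, 4 for sex in adolescents. By voom: 1 in adolescent males, 36 in adolescent females, 81 for their difference; 1 in adult males, 1 in adult females; 402 for age in males, 249 in females; 7 for sex in adolescents, 0 in adults. With 2 surrogate variables: 3 in adult females, 1105 for age in males, 226 in females. Without outlying libraries: 0 for the mean in adults and 250 for age in males. Without the libraries against their sex label: 1 for the sex difference in adolescents, 322 for age in males, 43 in females, 13 for sex in adolescents. With neighbour scores: 1 in adolescent males, 0 for the mean in adults, 51 for age in males, 5 for sex in adults. Beside each edgeR count of 0, between 1015 and 2786 genes (4.23% to 11.26%) lay at an unadjusted p under 0.05, where chance alone gives a share of 0.05. Leaving out 1 library at a time gave 0 to 0 for adolescent females, for the mean in adolescents, and for the differences in adults and of age, 0 to 7 for the difference in adolescents, 0 to 1 for adult females, 0 to 3 for the mean in adults, 106 to 1207 for age in males, 60 to 290 in females, 0 to 11 for sex in adolescents and 6 to 12 in adults. Reversed without the libraries against their sex label were Kdm5d (0.89) and Ddx3y (1.58) for age in females, and Xist for age in males, past the threshold only there (3.44), which those libraries alone had set. The 3.44 rests largely on adult control male replicate 6, with Xist at 53.33 CPM per total count against 0.38 to 9.01 CPM in the other adult control males. Reversed with the lncRNA share was the oxidative phosphorylation list for sex in adolescent controls (adjusted p = 1.13e-08 at the preset correlation, and without the share adjusted p = 0.764 with an estimated correlation). For the other changes the cause was not tested. FPKM values gave no alternative, since the raw counts were deposited. At the lowest depth 1 CPM is 59.1 counts, so depth limits the genes under 1 CPM most.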

Other observations

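The dopamine signalling list, the chromatin and DNA methylation list and the list of sex steroid receptors and synthesis passed in none of the 13 comparisons, with a smallest camera adjusted p of 0.244, 0.087 and 0.213. Among their members, Maob (0.46), which breaks down dopamine, rose with age in control males, and Dnmt3a, a DNA methyltransferase, fell by 0.40 on the log2 scale. With 1 library left out, Maob passed in 9 of 15 fits and Dnmt3a in 3 of 15. The stress axis receptor list passed in 1 comparison, age in control females (median 0.29; adjusted p = 0.0136, and adjusted p = 0.392 with an estimated correlation), and 12 of its 13 genes were higher at P90. Across 54 libraries the ribosomal protein score fell as the lncRNA share rose (r = -0.78; permutation p = 1e-05, the smallest the permutations can give; without the 2 farthest libraries -0.72).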
